A study of Mus musculus with 48 samples.

How the data were processed

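RNA was measured in 48 libraries from the thoracic mammary gland of mice that carry MMTV-rtTA, a doxycycline-dependent activator under a mammary tumour virus promoter, together with a responder under a tet operator. The responder was Esr1, which encodes estrogen receptor alpha, or CYP19A1, which encodes aromatase, the enzyme that makes estrogens. The deposited values are TPM, transcript abundances scaled to 1 fixed total per library, for 55487 genes, 21823 of them protein-coding, and every library reaches that total within rounding. Per the labels, total RNA was depleted of ribosomal RNA, made into stranded libraries and read on a NextSeq 550 as single ends of 75 bp, with at least 50 M reads stated. The submitters' processing notes list FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.9a, RSEM 1.3.1 and the mouse build mm10. TPM keep no library size, so the depth of each library above that stated minimum is unknown and no counting interval can be given. The annotation release is not named. Of the gene identifiers, 55094 matched GENCODE M21 with their version and 55394 without it, and positions are given from that release.

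The libraries fall into 16 groups of 3, named by model, age and induction. The titles call the libraries of a group biological replicates but do not say that each is a separate mouse, so the p-values measure the spread between these libraries. No sequencing run or preparation date is labelled. Titles of the 24- and 30-month libraries follow another naming pattern than those of the 12- and 18-month libraries, so a batch with that boundary would coincide with age.

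Genes with at least 1 TPM in at least 3 libraries were tested (20209 genes). Values were taken as log2(TPM + 1), and 1 linear model with a mean per group was fitted to all 48 libraries with limma 3.58.1 (moderated tests with an intensity trend, two-sided) in R 4.3.3. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The 18 comparisons set each induced group against the uninduced group of its age and model, older against younger uninduced glands, 30 against 24 months among long-induced glands, and the models against each other in uninduced and in long-induced glands, and took the difference between the models in their response to 1 week or to long induction. Folds are ratios on the log2(TPM + 1) scale and so lie nearer to 1 than ratios of TPM for scarce genes, and a gene listed at 0 in a whole group is given no fold. Values are means ± SD over libraries, and log2 changes carry the standard error (SE) of the fit. The Esr1 transcript was also compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries.

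Gene lists numbered 29 and comprised estrogen response, hormone-sensing luminal, luminal progenitor and alveolar, luminal epithelium, milk proteins and secretion, basal and myoepithelial, proliferation, interferon response, T cells, B cells, plasma cells, macrophages, granulocytes, white adipocytes, brown adipocytes, fatty acid synthesis, cholesterol synthesis, skeletal muscle, endothelium, fibroblasts and matrix, salivary gland, skin keratinocytes, Schwann cells and nerve, senescence-associated, oxidative phosphorylation, mitochondrially encoded, integrated stress response, immediate early and circadian clock. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Each list was also tested against all other genes with camera (limma), with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. Of 522 such tests, 212 passed with the preset correlation (108 higher, 104 lower) and 8 with an estimated one. The estimated correlations ran from 0.03 (salivary gland) to 0.973 (skeletal muscle), for most lists far above the preset 0.01. The preset value thus takes genes that vary together as nearly independent, and its p-values overstate the evidence for those lists. A list score is the mean log2(TPM + 1) of the tested members in a library, and scores were compared by two-sided exact permutation within strata of age and induction (174 tests, adjusted over the 29 lists of each).

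Genes named singly are a fixed set of key genes (Esr1, Pgr, Csn2 and others of mammary biology), the 8 largest rises and the 8 largest falls among genes that passed, whose groups did not overlap (or had 1 sign in every stratum) and that reached a mean of 2 TPM, and up to 4 members per list that passed with the largest change, or else the 2 most abundant. Predicted genes, pseudogenes, antibody and T cell receptor segments, and ribosomal protein and histone copies were counted and not named under that rule, and where 5 or fewer genes passed, all were to be named. Some genes that this rule selects are not reported here. The comparisons, tests, lists, this rule and the alternatives other than those given next as added were chosen before the data were examined.

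The alternatives were a pseudocount of 0.1, no filter, TPM rescaled by median-of-ratios factors, the replicate number as a block, the skeletal muscle score as a covariate, a fit of the compared groups alone, and leaving out each library in turn. Added after the data had been seen were a fit without the 9 libraries that had over 10% of TPM on genes that take ribosomal RNA reads, a fit without 1 library that nearly lacked Xist, the induction effect averaged over ages in each model, the difference between the models in their change with age, and the exact tests of list scores. Replicate numbers were checked for pairing: only between 30 and 24 months in the long-induced CYP19A1 model did all 3 same-number pairs correlate above 0.1 (0.106 to 0.251). The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold on the fitted scale. With 3 against 3 libraries it called 21% and 92% of them, and with 9 against 9 it called 90% and 100%. Simulated genes varied independently of each other, and scarce genes and the most variable genes were not among those changed. These shares therefore do not hold for such genes, or where the composition of libraries differs. The exact tests were run in R, and data preparation and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. No library was left out of the reported values.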

Results

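Gene expression was measured in the thoracic mammary gland of 2 mouse models with tet-op transgenes under MMTV-rtTA. Doxycycline induces Esr1, the estrogen receptor alpha gene, in the first and CYP19A1, the aromatase gene, in the other. Each model has 8 groups of 3 libraries. Uninduced glands were taken at 12, 18 and 24 months of age. Induced glands were taken after 1 week at 12 or 18 months, after 6 or 12 months at 24 months, and after 18 months at 30 months. No uninduced glands of 30 months were measured. No group had doxycycline without a responder transgene, so the induction comparisons cannot tell the drug from the transgene. TPM do not keep the depth of a library, which is unknown beyond the stated minimum of 50 M reads. Between 11028 and 17605 genes reached 1 TPM in a library.

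Noncoding RNA and skeletal muscle genes differed widely between libraries. The signal recognition particle RNA genes took 31.4% of TPM in the median library (11.3% to 40.2%), mitochondrial ribosomal RNA 16.5% (5.26% to 29.9%) and protein-coding genes 33.1% (15.9% to 38.8%). Reads of cytoplasmic ribosomal RNA align to CT010467.1, AY036118 and Lars2, which took 0.0752% of TPM in the median library but over 10% in 9 libraries. Of these, 7 were CYP19A1 libraries: replicates 1 and 3 of the uninduced 12-month glands, all 3 replicates after 1 week of induction at 12 months, replicate 1 of the uninduced 18-month glands and replicate 3 of the uninduced 24-month glands. The other 2 were replicate 3 of the Esr1 glands induced for 6 months and for 18 months. The highest share, 67.2%, was in replicate 1 of the uninduced 12-month CYP19A1 glands. Median-of-ratios factors, which offset such shares, ranged from 0.312 to 1.46. The skeletal muscle score ranged from 3.55 to 11.14 on the log2 scale, and Acta1, the skeletal muscle actin gene, from 48.6 to 8710 TPM.

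**Figure D1:**
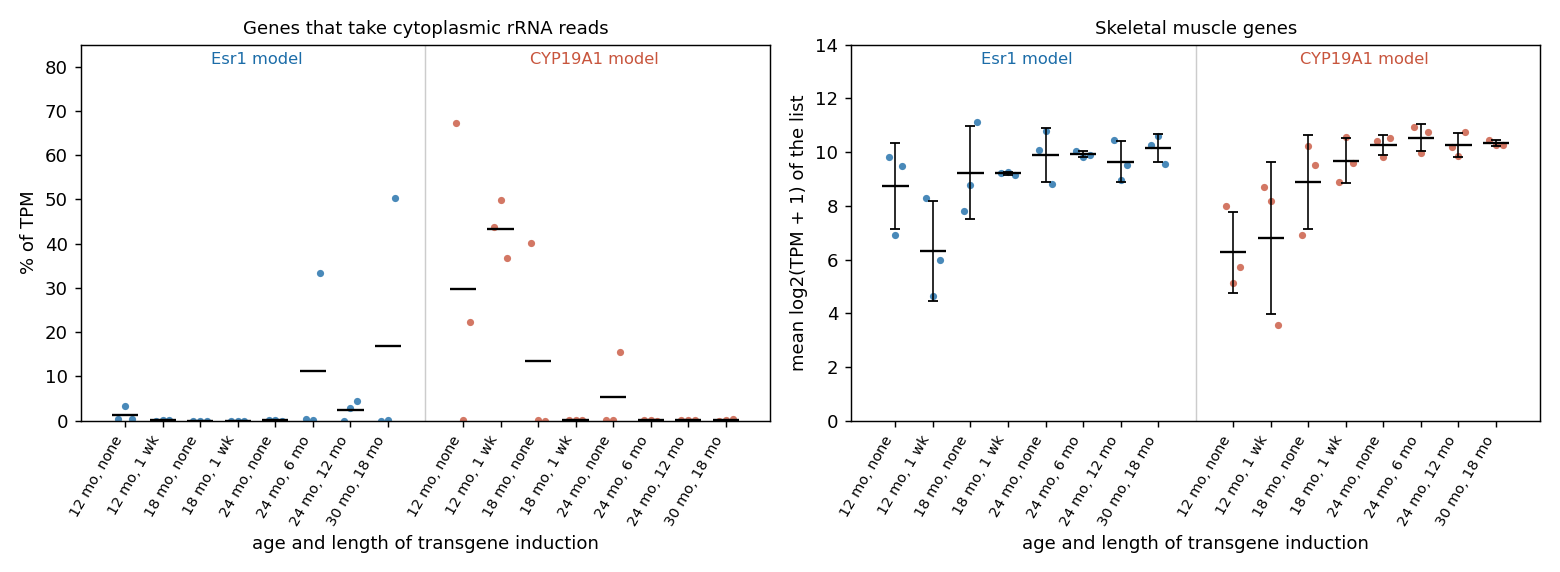
Left, percent of TPM on genes that take cytoplasmic ribosomal RNA reads, and right, mean log2(TPM + 1) of 16 skeletal muscle genes, for each library by age and length of induction (points, libraries; black bars, means of 3; whiskers on the right, SD). The 12-month CYP19A1 glands hold 5 of the 9 libraries above 10% on the left and, with the 12-month Esr1 glands induced for 1 week, the lowest mean muscle scores on the right.

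The Esr1 transcript was compared in the Esr1 model to ask how far induction raised it. Esr1 (ENSMUSG00000019768.16, chromosome 10, 4611593 to 5005614, mm10) lay at 14.6 ± 3.77 TPM after 1 week at 12 months against 12.0 ± 2.62 TPM without. The log2 change was 0.26 (95% interval -0.34 to 0.86, n = 3, exact permutation p = 0.4). At 18 months it lay at 17.9 ± 6.93 against 11.8 ± 3.11 TPM (0.53, -0.07 to 1.13, n = 3, exact p = 0.3). At 24 months it lay at 13.4 ± 2.91 TPM without induction. After 6 months of induction it lay at 11.3 ± 2.16 TPM (-0.22, -0.82 to 0.38, exact p = 0.4), and after 12 months at 10.5 ± 3.78 TPM (-0.36, -0.96 to 0.24, exact p = 0.5). None of the 4 differences exceeded the spread between libraries, and 0.1 is the smallest p that 3 against 3 libraries allow. Averaged over the ages, the change was 0.17, and -0.01 after median-of-ratios rescaling. Over all 48 libraries Esr1 ranged from 5.61 to 25.9 TPM. Mouse Cyp19a1 stayed at or below 0.29 TPM in every library. The CYP19A1 transgene carries the symbol of the human gene, whose reads need not be counted there. Reads of the Esr1 transgene need not all be counted under mouse Esr1 either, and RNA was taken from the gland as a whole, of which epithelium is a part.

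**Figure D2:**
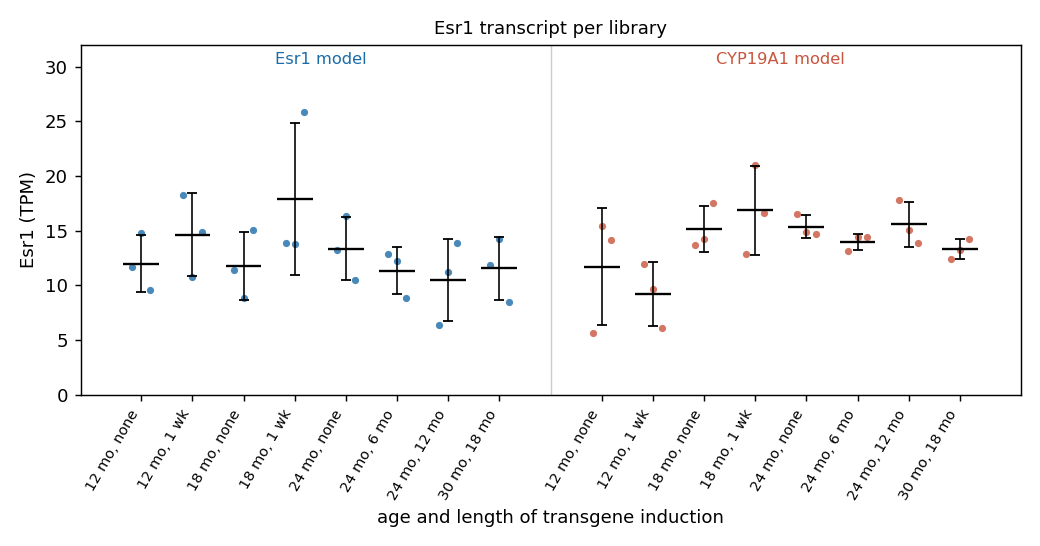
Esr1 in TPM for each library by age and length of induction in both models (points, libraries; black bars, means of 3; whiskers, SD). Induced and uninduced libraries of the Esr1 model overlap at 12, 18 and 24 months, within 6.39 to 25.9 TPM.

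Which genes responded to induced Esr1 is asked by 4 comparisons in the Esr1 model. After 1 week at 12 months, Cybrd1, which encodes an iron-reducing cytochrome, rose to 2.85 ± 0.944 from 0.453 ± 0.025 TPM (2.59-fold, n = 3, limma adjusted p = 0.0216). The small nucleolar RNA Gm22589 lay at 32.4 ± 6.91 TPM against being listed at 0 (adjusted p = 0.0109). Of 16 skeletal muscle genes 0 passed over all genes and 16 were lower adjusted over the list alone. Their median was -2.45 (camera adjusted p = 1.97e-31, adjusted p = 0.0393 with an estimated correlation), with Acta1 at 516 ± 637 against 2014 ± 1361 TPM. Of 9 brown adipocyte genes 0 passed over all genes and 5 were lower adjusted over the list alone. Their median was -1.66 (camera adjusted p = 2.88e-15, adjusted p = 0.0109 with an estimated correlation). With rescaled TPM neither the muscle nor the brown adipocyte genes passed with an estimated correlation (camera adjusted p = 0.33 for each). The 37 proliferation genes lay higher, with 0 past the test over all genes or adjusted over the list alone. Their median was 0.79 (camera adjusted p = 1.87e-11, adjusted p = 0.672 with an estimated correlation). Epithelial genes lay higher with them, luminal with 0 of 16 past the test and a median of 0.74 (camera adjusted p = 0.0182, adjusted p = 0.711 with an estimated correlation). Basal and myoepithelial genes had 0 of 14 and a median of 0.57 (camera adjusted p = 0.0223, adjusted p = 0.711 with an estimated correlation).

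After 1 week at 18 months limma called 0 genes for Esr1 (253 at an unadjusted p under 0.05). The 3 tested salivary gland genes were higher, 0 over all genes and 2 adjusted over the list alone. Their median was 0.87 (camera adjusted p = 1.76e-08, adjusted p = 2.53e-05 with an estimated correlation), with the kallikrein gene Klk1 at 41.7 ± 69.5 against 0.153 ± 0.032 TPM. Much of this lay in induced replicate 3, with a salivary score of 3.62 against 1.89 and 2.33 in replicates 1 and 2. Proliferation genes, with a median of 0.79 at 12 months, had one of -0.08 at 18 months. Here too 0 of 37 passed over all genes (camera adjusted p = 5.08e-05, adjusted p = 0.928 with an estimated correlation). The difference between these ages was not tested. At 24 months limma called 0 genes after 6 months of induction (235 at an unadjusted p under 0.05). After 12 months the pseudogene BC002163 alone rose (40.7 ± 7.87 against 5.46 ± 2.33 TPM, 6.64-fold, adjusted p = 0.00427). The lower change of BC002163 with age in the Esr1 than in the CYP19A1 model (log2 difference -4.37) rests on the same uninduced 24-month glands. Of 11 B cell genes 0 passed over all genes after 6 or 12 months, and 1 was lower adjusted over the list alone after 6 months. Their median was -0.92 after 6 months (camera adjusted p = 6.07e-17, adjusted p = 0.107 with an estimated correlation). It was -0.96 after 12 months (camera adjusted p = 2.99e-19, adjusted p = 0.0618 with an estimated correlation). Both comparisons, and the one with age, use the same uninduced 24-month glands, with B cell scores of 3.33 and 3.05 in replicates 1 and 2 and 1.20 in replicate 3. Milk genes lay higher, with 0 of 17 past the test after 6 or 12 months. After 6 months the median was 0.68 (camera adjusted p = 0.000107, adjusted p = 0.914 with an estimated correlation). After 12 months it was 1.79 (camera adjusted p = 1.73e-13, adjusted p = 0.232 with an estimated correlation). The uninduced milk scores were 1.65, 1.86 and 7.62. Estrogen response genes, which include Greb1, Pgr and Areg, had 0 of 26 members past the test in each of the 4 comparisons. Adjusted over the list alone, 1 was higher after 1 week at 12 months. Their medians were 0.34, 0.18, -0.01 and 0.00. Pgr lay at 5.26 ± 3.75 against 3.93 ± 2.11 TPM after 1 week at 12 months (adjusted p = 0.849).

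The counts of the 4 Esr1 comparisons were 2, 0, 0 and 1 of 20209 genes, with 1114, 253, 235 and 279 at an unadjusted p under 0.05. After rescaling limma called 0 genes in each. The log2 change of BC002163 was 2.73, and 2.60 rescaled (limma adjusted p = 0.0769). The median of all genes moved by 0.22 at 12 months and by 0.14 at 18 months. Averaged over the ages, limma called 0 genes (1028 at an unadjusted p under 0.05, smallest adjusted p 0.0811). Single libraries decided these counts. At 12 months there were 0 genes without any 1 uninduced library or without induced replicate 2, 7 without induced replicate 1 and 4 without induced replicate 3. At 18 months there were 4 without uninduced replicate 2, and 10, 1 and 3 without induced replicates 1, 2 and 3. For 6 months of induction there were 3 and 6 without uninduced replicates 2 and 3, and 1 and 4 without induced replicates 1 and 2. For 12 months there were 3, 0 and 9 without uninduced replicates 1, 2 and 3, and 4 and 0 without induced replicates 1 and 2. The averaged effect had 11 genes without replicate 1 of the 18-month induced glands and 7 without replicate 3 of the 12-month induced glands. It had 2 without 12-month induced replicate 2 or 18-month induced replicate 3. It had 1 without uninduced replicate 1 at 12, 2 at 18 or 3 at 24 months, 18-month induced replicate 2, or 6-month induced replicate 3.

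The same question for induced aromatase is asked by 4 comparisons in the CYP19A1 model. After 12 months of induction, 3 genes of cornified skin rose, calls that were each lost without at least 1 library. Krt6a, a stress keratin, rose to 3.55 ± 1.44 from 0.347 ± 0.32 TPM (3.33-fold, n = 3, limma adjusted p = 0.00695). Asprv1, a protease of the cornified layer, rose 3.41-fold (adjusted p = 0.0354) and Sprr1a, a cornified envelope protein, 2.99-fold (adjusted p = 0.0142). The noncoding RNA AC241534.1 fell to 0.384-fold (log2 change -1.38, adjusted p = 0.00695). Rescaled, its change was -1.39 and did not pass (adjusted p = 0.309). Of 7 skin keratinocyte genes 0 passed over all genes and 5 were higher adjusted over the list alone. Their median was 1.41 (camera adjusted p = 4.93e-20, adjusted p = 0.000214 with an estimated correlation). Most of this lay in induced replicate 3, with a skin score of 3.89 against 1.48 and 1.10 in replicates 1 and 2 and at most 0.94 without induction. With a pseudocount of 0.1, or in a fit of the compared groups alone, 0 genes were called. After 6 months limma called 0 genes (261 at an unadjusted p under 0.05). B cell genes lay lower, 0 of 11, with a median of -0.76 (camera adjusted p = 1.79e-13, adjusted p = 0.127 with an estimated correlation). Plasma cell genes lay lower, 0 of 12, with a median of -1.23 (camera adjusted p = 9.24e-13, adjusted p = 0.127 with an estimated correlation).

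After 1 week at 12 months limma called 0 genes for CYP19A1 (1370 at an unadjusted p under 0.05). Of 15 fatty acid synthesis genes 0 passed over all genes and 8 were lower adjusted over the list alone. Their median was -1.05 (camera adjusted p = 1.01e-07, adjusted p = 0.658 with an estimated correlation), in a group whose 3 libraries carry 36.7% to 49.9% of TPM on ribosomal RNA. Areg, an epithelial growth factor that estrogen induces, lay at 0.283 ± 0.14 against 14.5 ± 8.04 TPM there (adjusted p = 0.548). At 18 months limma called 0 genes (295 at an unadjusted p under 0.05). Estrogen response genes had 0 of 26 members past the test in each of the 4 comparisons, with medians of -0.37, 0.10, -0.00 and 0.11. Adjusted over the list alone, 1 was lower after 1 week at 12 months.

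The counts of the 4 CYP19A1 comparisons were 0, 0, 0 and 4 genes, with 228 at an unadjusted p under 0.05 for 12 months of induction. The median of all genes moved by -0.32 after 1 week at 12 months and by 0.12 after 12 months. Averaged over the ages, limma called 0 genes (232 at an unadjusted p under 0.05), and 1 without replicate 2 of the glands induced for 12 months. At 12 months 12421 genes were called without uninduced replicate 1, the library with the highest ribosomal RNA share, and 1 without induced replicate 1 or 3. At 18 months 1 gene was called without uninduced replicate 1 or induced replicate 2. For 6 months of induction 2 and 3 genes were called without uninduced replicates 2 and 3, and 1 without induced replicate 1 or 3. For 12 months there were 0 and 2 genes without uninduced replicates 1 and 2, and 8 without induced replicate 3.

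Whether the models differed in their response was tested as the difference of their effects. For 1 week of induction limma called 0 genes (1297 at an unadjusted p under 0.05), and the median of all genes differed by 0.30. Skeletal muscle genes lay lower in the Esr1 response, 0 of 16, with a median of -1.91 (camera adjusted p = 6.36e-30, adjusted p = 0.097 with an estimated correlation). For long induction at 24 months limma called 0 genes (236 at an unadjusted p under 0.05). Skin keratinocyte genes had 0 of 7 past the test there and a median of -1.13 (adjusted p = 0.0948 with an estimated correlation). For 1 week 6988 genes were called without replicate 1 of the uninduced 12-month CYP19A1 glands. Without induced replicate 1 of the 18-month Esr1 glands 6 were called, and 1 without uninduced replicate 2. For long induction 1 gene was called without uninduced replicate 3 or 6-month induced replicate 1 of either model.

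Changes with age without induction were compared in each model. In the Esr1 model, genes of fatty acid synthesis fell from 12 to 24 months. Fasn, fatty acid synthase, fell to 151 ± 33.3 from 1159 ± 497 TPM (0.138-fold, log2 change -2.85, SE 0.58, n = 3, limma adjusted p = 0.00713). Acaca, acetyl-CoA carboxylase, fell to 47.1 ± 17.8 from 289 ± 106 TPM (0.166-fold, adjusted p = 0.00323). Elovl6, a fatty acid elongase, fell to 0.102-fold (adjusted p = 0.00318) and Acly, ATP citrate lyase, to 0.186-fold (adjusted p = 0.0277). Of 15 members 5 fell over all genes and 10 adjusted over the list alone. Their median was -1.62 (camera adjusted p = 4.57e-18, adjusted p = 0.0354 with an estimated correlation). With rescaled TPM the list did not pass with an estimated correlation (camera adjusted p = 0.282). Slc25a1, the mitochondrial citrate carrier that feeds this pathway, fell to 0.189-fold (adjusted p = 0.00218), the phospholipase gene Gdpd3 to 0.068-fold (adjusted p = 0.00295) and Cyp2e1 to 0.104-fold (adjusted p = 0.0439). Of 13 mitochondrially encoded genes mt-Nd3 (0.318-fold) and mt-Nd4l (0.2-fold) fell, 2 over all genes and 11 adjusted over the list alone. Their median was -1.24 (camera adjusted p = 1.36e-14, adjusted p = 0.0748 with an estimated correlation).

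Other genes rose from 12 to 24 months in the Esr1 model. Sfrp5, a secreted Wnt inhibitor, rose to 32.7 ± 10.3 from 1.94 ± 0.505 TPM (11.2-fold, n = 3, limma adjusted p = 0.000858). Cep85, a centrosome gene, rose 7.37-fold (adjusted p = 0.0003), the retinal dehydrogenase gene Aldh1a1 4.04-fold (adjusted p = 0.0124) and the calcium channel gene Cacna1e 3.89-fold (adjusted p = 0.0212). The myeloid receptor gene Cd300ld3 rose 3.83-fold (adjusted p = 5.22e-11), Rmrp, the RNA of a ribonuclease, 3.41-fold (adjusted p = 0.0197) and Synpo2 3.26-fold (adjusted p = 0.00719). Its neighbour in name, Cd300ld5, lay at 2.7 ± 2.13 TPM against being listed at 0 (adjusted p = 0.0003). Of 11 B cell genes 0 passed over all genes and 9 were higher adjusted over the list alone. Their median was 1.44 (camera adjusted p = 1.65e-14, adjusted p = 0.0748 with an estimated correlation). Of 11 senescence-associated genes 0 passed over all genes and 2 were higher adjusted over the list alone. Their median was 0.80 (camera adjusted p = 3.95e-05, adjusted p = 0.293 with an estimated correlation).

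In all 66 genes rose and 50 fell in the Esr1 model (1552 at an unadjusted p under 0.05). After rescaling 193 rose and 170 fell, among them 66 and 45 of the same genes. A fit of the compared groups alone called 24 genes, of those named Sfrp5 and Cd300ld3, and a fit without the libraries rich in ribosomal RNA called 266. Left out singly, 12-month replicates 1, 2 and 3 gave 72, 62 and 71 genes, and 24-month replicates 1 and 2 gave 68 and 75. Without 12-month replicate 1 the adjusted p was 0.0693 for Fasn and 0.0533 for Elovl6, while that of Acaca was at most 0.0434 without any 1 library. Of 17 named calls 7 held without any 1 library, those of Acaca, Slc25a1, Gdpd3, Sfrp5, Cep85, Cd300ld3 and Cd300ld5. From 12 to 18 months limma called 0 genes (558 at an unadjusted p under 0.05), 1 without 12-month replicate 1 and 2 without 18-month replicate 2. Fatty acid synthesis genes lay lower already, with 0 of 15 past the test over all genes and 9 adjusted over the list alone. Their median was -1.24 (camera adjusted p = 1.19e-20, adjusted p = 0.00896 with an estimated correlation). White adipocyte genes lay lower with them, with a median of -0.89 (adjusted p = 0.0529 with an estimated correlation). Of 9 brown adipocyte genes 0 passed over all genes and 5 were lower adjusted over the list alone. Their median was -1.33 (camera adjusted p = 2.02e-14, adjusted p = 0.00896 with an estimated correlation). With rescaled TPM neither fatty acid synthesis nor brown adipocyte genes passed with an estimated correlation (camera adjusted p = 0.0872 for each).

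In the CYP19A1 model skeletal muscle genes rose from 12 to 24 months. All 16 rose over all genes and adjusted over the list alone. Their median was 3.98 (camera adjusted p = 1.11e-18, adjusted p = 0.515 with an estimated correlation). After rescaling 0 passed and the median was 3.58. The 12-month replicates 1, 2 and 3 had muscle scores of 7.97, 5.13 and 5.71, and replicates 1 and 3 are rich in ribosomal RNA. Acta1 reached 5475 ± 1199 from 441 ± 476 TPM (18.0-fold, log2 change 4.17, SE 1.00, n = 3, limma adjusted p = 0.0103). The sarcomere genes Nrap, Mybpc2, Myh2, Neb and Tnni2 rose 17.2- to 18.4-fold. Myelin genes of Schwann cells rose with muscle, 3 of 8 over all genes and 7 adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). Of these Mbp rose 2.88-fold and Prx 2.51-fold. Of 18 oxidative phosphorylation genes 2 rose over all genes and 15 adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). Of these Ndufa9 rose 1.88-fold (adjusted p = 0.0482). Single members of other lists rose too, Jun 2.30-fold (adjusted p = 0.0155), Hspb8 2.93-fold (adjusted p = 0.0189) and Tspan8 3.68-fold (adjusted p = 0.0129).

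The mitochondrial tRNA mt-Tl1 lay at 71.5 ± 24.6 TPM against being listed at 0 (limma adjusted p = 0.0173), and Mir1190 fell to 0.281-fold (adjusted p = 0.0439). B cell genes lay higher at 24 months in this model, 0 of 11 over all genes and 6 adjusted over the list alone. Their median was 1.06 (adjusted p = 0.751 with an estimated correlation). Fatty acid synthesis genes lay lower, 0 of 15, with a median of -0.53 (camera adjusted p = 3.03e-06, adjusted p = 0.616 with an estimated correlation). Fasn lay at 529 ± 118 against 913 ± 192 TPM (adjusted p = 0.583). In all 844 genes rose and 13 fell (2961 at an unadjusted p under 0.05), 98.5% upward, and the median of all genes moved by 0.22. After rescaling 37 rose and 28 fell, 56.9% upward, among them 31 and 7 of the same genes. The count was 3 in a fit of the compared groups alone, 12 with the muscle score as a covariate and 7 without the libraries rich in ribosomal RNA, where 1 library of 12 months is left and its spread is taken from the other groups. It was 3374 without 12-month replicate 2, and 239 and 264 without 24-month replicates 1 and 3. Of 14 named calls those of Nrap and Neb held without any 1 library, and 0 held in every other setting.

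From 12 to 18 months in the CYP19A1 model limma called 2 genes. The small RNA gene Gm27913 lay at 1.69 ± 0.382 TPM against being listed at 0 (limma adjusted p = 0.0187). Of 16 skeletal muscle genes 0 passed over all genes and 16 were higher adjusted over the list alone. Their median was 2.63, and 2.31 after rescaling (adjusted p = 0.369 with an estimated correlation). The median of all genes moved by 0.18, 1133 genes had an unadjusted p under 0.05, and both calls were lost after rescaling. There were 4, 11 and 0 genes without 12-month replicates 1, 2 and 3, and 0, 1 and 0 without 18-month replicates 1, 2 and 3. Whether the models aged differently was tested as the difference of their changes. For 18 against 12 months limma called 0 genes (708 at an unadjusted p under 0.05, median of all genes -0.19). For 24 against 12 months 4 genes had a higher and 4 a lower change in the Esr1 model.

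Glands of 30 months after 18 months of induction were compared with glands of 24 months after 12 months, a step in which age and length of induction move together. In the Esr1 model Lep, the leptin gene of fat cells, fell to 14.4 ± 5.04 from 327 ± 167 TPM (0.05-fold, log2 change -4.32, SE 0.85, n = 3, limma adjusted p = 0.026). Sfrp5 fell to 4.28 ± 0.482 TPM (0.107-fold, adjusted p = 0.0138), Npr3, a natriuretic peptide receptor, to 0.08-fold (adjusted p = 0.0433) and Adamts5, a matrix protease, to 0.173-fold (adjusted p = 0.0268). Gabrr2, Cfb, Anxa5 and Syp fell to between 0.235- and 0.255-fold. Of 14 white adipocyte genes Lep alone fell over all genes, and 6 adjusted over the list alone. Their median was -0.94 (camera adjusted p = 0.000764, adjusted p = 0.68 with an estimated correlation). Of 16 fibroblast and matrix genes 0 fell over all genes and 7 adjusted over the list alone. Their median was -1.34 (camera adjusted p = 5.18e-06, adjusted p = 0.619 with an estimated correlation).

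In all 2 genes rose and 26 fell at 30 months in the Esr1 model (3208 at an unadjusted p under 0.05), 7.1% upward, and the median of all genes moved by -0.36. After rescaling 5 rose and 16 fell, 23.8% upward, among them 2 and 11 of the same genes. The count was 0 in a fit of the compared groups alone, 105 with the muscle score as a covariate and 85 without the libraries rich in ribosomal RNA. There were 4 and 17 genes without 24-month replicates 1 and 2, and 2, 5 and 7 without 30-month replicates 1, 2 and 3. Of the 8 named calls 0 held in every fit that left out a library. In the CYP19A1 model limma called 0 genes for the same step (332 at an unadjusted p under 0.05), and 1 with replicate number as a block. Of 7 skin keratinocyte genes 0 passed over all genes and 6 were lower adjusted over the list alone. Their median was -1.44 (camera adjusted p = 1.97e-13, adjusted p = 0.00359 with an estimated correlation), with Krt10 at 0.977 ± 0.206 against 9.76 ± 14.9 TPM. The 24-month group is the one whose replicate 3 alone had a high skin score (3.89), so this fall and the rise after 12 months of induction share these 3 libraries. The median of all genes moved by -0.18. Without 24-month replicates 1 and 3 and 30-month replicate 3, 1, 5 and 1 genes were called. The difference between the models in this step passed for 1 gene, Cd300ld3.

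The uninduced glands of both models were compared over 12, 18 and 24 months to ask how the lines differ before induction. Of the named genes, 2 of the interferon-inducible cluster on chromosome 1 had the smallest p-values. Ifi202b (173962568 to 173982744, mm10) lay at 0.584 ± 0.407 TPM in the Esr1 and 16.6 ± 7.11 TPM in the CYP19A1 model (0.095-fold, n = 9, limma adjusted p = 2.17e-16). Its neighbour Mndal (173849126 to 173942491) lay at 21.2 ± 5.79 against 3.21 ± 1.26 TPM (5.38-fold, adjusted p = 9.25e-13). Kpna2, a nuclear import receptor (5.32-fold, adjusted p = 1.43e-10), and Gstp2, a glutathione transferase (4.26-fold, adjusted p = 1.82e-05), were higher in the Esr1 model. Gchfr, a regulator of GTP cyclohydrolase (0.186-fold, adjusted p = 1.15e-10), and Psmc3ip, a meiotic recombination factor (0.336-fold, adjusted p = 5.33e-09), were lower. Lower too were the zinc finger genes Zfp973 (0.231-fold) and Zfp966 (0.266-fold), Vsig2, the MHC class I gene H2-Q2 (0.362-fold) and Rarres1 (0.4-fold). Glycam1, a mucin secreted in milk, was higher at 1325 ± 2758 against 6.25 ± 10.7 TPM (28.7-fold, adjusted p = 0.0149). So were Snord45c (8.16-fold), the connexin gene Gjb6 (6.3-fold), Bcl2l15 (5.1-fold) and Pigr, which carries antibodies across epithelium (4.82-fold).

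Of 23 interferon response genes 5 were higher in uninduced glands of the Esr1 model over all genes and 14 adjusted over the list alone. Their median was 0.51 (camera adjusted p = 3.98e-08, adjusted p = 0.789 with an estimated correlation). Of these Ifit3 was 2.83-fold (limma adjusted p = 1.9e-06) and Ifit1 2.08-fold higher, with Ifi44 and Gbp3 also past the test. Of 37 proliferation genes 3 were higher over all genes and 15 adjusted over the list alone. Their median was 0.54 (camera adjusted p = 3.98e-08, adjusted p = 0.789 with an estimated correlation), with Prc1 2.29-fold higher (adjusted p = 0.00586) and Bub1b and Tpx2 past the test. Of 17 milk genes Glycam1 alone passed, and 6 adjusted over the list alone. Their median was 1.3 (adjusted p = 0.856 with an estimated correlation). Csn2, beta-casein, lay at 3830 ± 4002 against 474 ± 751 TPM (adjusted p = 0.137) and Esr1 at 12.4 ± 2.61 against 14.1 ± 3.41 TPM (adjusted p = 0.666). Of 26 estrogen response genes Stc2 was lower (0.475-fold, adjusted p = 0.00642), 1 over all genes and 1 adjusted over the list alone (adjusted p = 0.899 with an estimated correlation).

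In all 398 genes were higher and 198 lower in uninduced glands of the Esr1 model (3583 at an unadjusted p under 0.05), 66.8% higher, and the median of all genes differed by 0.10. After rescaling 1813 were higher and 1566 lower, 53.7% higher, among them 388 and 198 of the same genes. Without the libraries rich in ribosomal RNA, where 1 CYP19A1 library of 12 months is left, 262 were higher and 2307 lower. The count was 211 in a fit of the compared groups alone and 1771 with the muscle score as a covariate. It was 1260 without replicate 3 of the 18-month Esr1 glands, and 1020, 1094 and 1349 without replicates 1, 2 and 3 of the 12-month CYP19A1 glands. Of 27 named calls 17 held without any 1 library, among them Ifi202b, Mndal, Kpna2, Gchfr, Psmc3ip and Ifit3. Those of Glycam1, Gjb6, Pigr, Rarres1, Ifi44, Gbp3, Bub1b and Tpx2 were lost without at least 1.

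**Figure D3:**
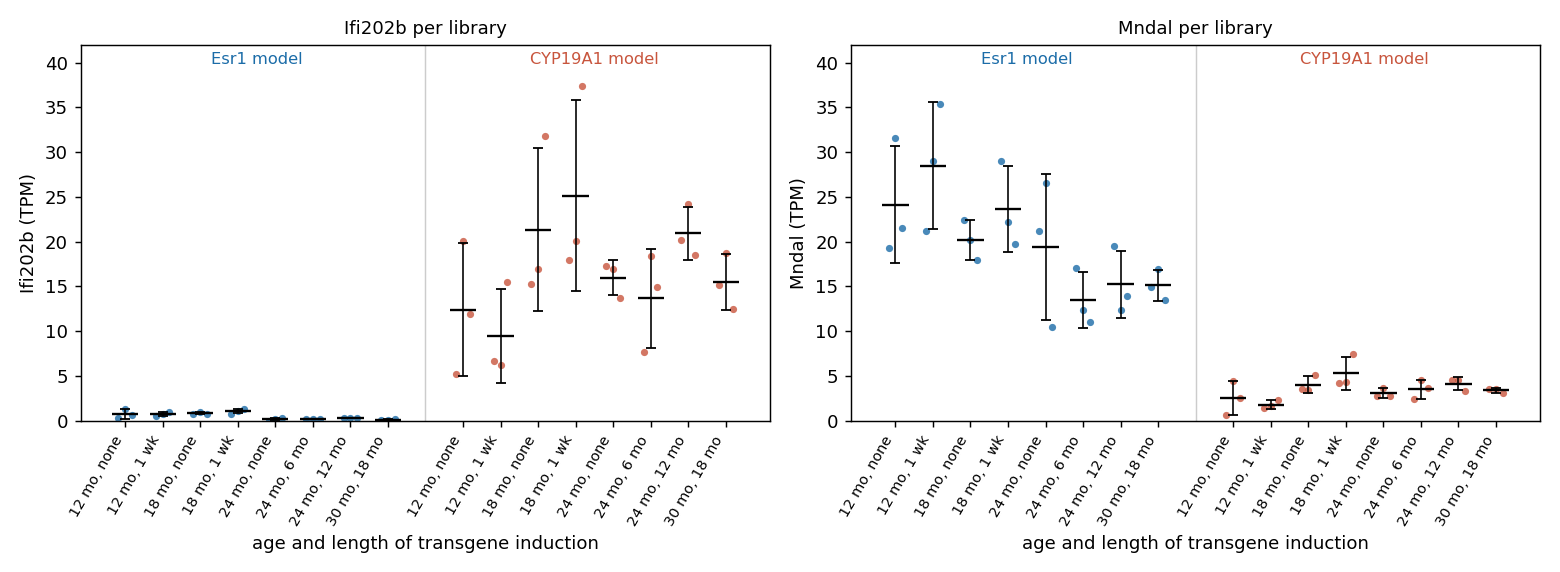
Ifi202b (left) and Mndal (right) in TPM for each library by age and length of induction (points, libraries; black bars, means of 3; whiskers, SD). In uninduced glands Ifi202b averaged 0.584 TPM in the Esr1 and 16.6 TPM in the CYP19A1 model, and Mndal 21.2 and 3.21 TPM.

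The long-induced glands of both models were compared over 6, 12 and 18 months of induction to ask how the models differ after prolonged induction. The lines also differ without induction, and these values do not show that either transgene was expressed. Milk protein genes were higher in the Esr1 model. Csn2 lay at 2231 ± 2181 against 113 ± 194 TPM (20.6-fold, log2 change 4.36, SE 1.24, n = 9, limma adjusted p = 0.0329). Wap, whey acidic protein, lay at 752 ± 945 against 23.1 ± 52.3 TPM (31.5-fold, adjusted p = 0.0106). Glycam1 was 38.5-fold (adjusted p = 0.00492), the casein Csn1s1 7.61-fold (adjusted p = 0.0495) and Lao1 6.49-fold higher (adjusted p = 0.037). The casein Csn1s2a lay at 3976 ± 3988 against 214 ± 389 TPM (adjusted p = 0.0419). Of 17 milk genes 8 were higher and 1 lower over all genes, and 10 and 1 adjusted over the list alone. Their median was 1.85 (camera adjusted p = 5.24e-13, adjusted p = 0.361 with an estimated correlation). After rescaling 10 were higher and 1 lower. Uninduced 24-month glands held mean Csn2 of 3070 ± 5314 (Esr1) against 15.4 ± 14.8 TPM (CYP19A1). Their milk scores were 1.65, 1.86 and 7.62 against 2.25, 2.79 and 3.22, so the high Esr1 mean rests on replicate 3. In the models' response to long induction at 24 months 0 of 17 milk genes differed. The median difference was 0.83 (camera adjusted p = 0.0151, adjusted p = 0.994 with an estimated correlation).

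In long-induced glands of the Esr1 model 8 of 15 fatty acid synthesis genes were lower over all genes and 11 adjusted over the list alone. Their median was -1.03 (camera adjusted p = 1.99e-10, adjusted p = 0.361 with an estimated correlation). Fasn lay at 144 ± 87.3 against 560 ± 212 TPM (0.24-fold, n = 9, limma adjusted p = 5.25e-05). Elovl6 was 0.274-fold (adjusted p = 0.000698), Acaca 0.357-fold (adjusted p = 0.000629) and Scd1, stearoyl-CoA desaturase, 0.382-fold (adjusted p = 0.00167). Uninduced 24-month glands differed the same way, with fatty acid synthesis scores of 5.57, 5.69 and 5.75 (Esr1) against 6.46, 6.74 and 6.08 (CYP19A1). Fasn lay there at 151 ± 33.3 against 529 ± 118 TPM. The models' responses to long induction at 24 months did not differ past the test for this list (median -0.21, camera adjusted p = 0.994 with an estimated correlation). In the long-induced glands 5 of 18 oxidative phosphorylation genes were lower over all genes, all 18 adjusted over the list alone, and 1 after rescaling. Their median was -0.49 (camera adjusted p = 3.74e-10, adjusted p = 0.508 with an estimated correlation). Of these Sdhb was 0.663-fold, Uqcrc1 0.678-fold and Sdha 0.681-fold. Of 9 brown adipocyte genes 2 were lower over all genes and 4 adjusted over the list alone. Their median was -0.74 (camera adjusted p = 0.000747, adjusted p = 0.508 with an estimated correlation). The uncoupling protein gene Ucp1 lay at 21.9 ± 56.2 against 63.7 ± 55.4 TPM (0.097-fold, adjusted p = 0.0162), and the potassium channel gene Kcnk3 was 0.546-fold (adjusted p = 0.0112). Of 12 plasma cell genes 3 were lower over all genes and 4 adjusted over the list alone. Their median was -0.25 (camera adjusted p = 0.128, adjusted p = 0.792 with an estimated correlation). They were the antibody constant region genes Ighg1 (0.191-fold, adjusted p = 0.00154), Ighg2b (0.23-fold, adjusted p = 0.00243) and Ighg2c (0.35-fold, adjusted p = 0.0178). Among 173 antibody segments 3 were higher and 7 lower.

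Of 13 hormone-sensing luminal genes 1 was higher and 2 lower over all genes in long-induced glands of the Esr1 model, and 2 and 4 adjusted over the list alone. Their median was -0.36 (camera adjusted p = 0.372, adjusted p = 0.794 with an estimated correlation). Calca was 6.2-fold higher (limma adjusted p = 0.034). The growth factor gene Ptn (0.27-fold, adjusted p = 0.00595) and Foxa1, a cofactor of the estrogen receptor (0.552-fold, adjusted p = 0.0388), were lower. Of 26 estrogen response genes Stc2 (0.452-fold, adjusted p = 0.00243) and Foxa1 were lower, 2 over all genes, and 1 higher and 5 lower adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.608, adjusted p = 0.868 with an estimated correlation). Esr1 itself lay at 11.1 ± 2.66 in the Esr1 model against 14.3 ± 1.56 TPM (adjusted p = 0.258). Pgr, a target of the receptor, lay at 2.47 ± 2.16 against 6.39 ± 3.55 TPM (adjusted p = 0.053). The oldest uninduced glands leaned the same way, with Foxa1 at 1.08 ± 0.934 (Esr1) against 2.42 ± 0.567 TPM (CYP19A1). Pgr lay there at 2.57 ± 1.89 against 5.76 ± 2.66 TPM. The models' responses to long induction did not differ past the test for Foxa1, Ptn or Pgr. Their log2 differences were -0.15 (SE 0.53), -0.57 (SE 0.93) and -0.23 (SE 0.75). Of 12 luminal progenitor and alveolar genes Wfdc18 alone was higher over all genes in long-induced glands (5.38-fold, adjusted p = 0.0373), and 6 adjusted over the list alone. Their median was 0.96 (camera adjusted p = 2.73e-06, adjusted p = 0.508 with an estimated correlation).

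Other list members also differed in long-induced glands. The stress gene Ddit4 was 2.08-fold (limma adjusted p = 0.0193), Ifit3 1.75-fold (adjusted p = 0.0123) and Prc1 1.87-fold higher in the Esr1 model (adjusted p = 0.0464). Angptl8, an insulin-induced secreted factor of fat, was lower (0.187-fold, adjusted p = 0.00145), as was the glucose transporter gene Slc2a4 (0.591-fold, adjusted p = 0.0218). The endothelial receptor gene Kdr (0.615-fold, adjusted p = 0.0267), the sterol desaturase gene Sc5d (0.571-fold, adjusted p = 0.0454) and mt-Nd4l (0.526-fold, adjusted p = 0.0383) were lower. Ifi202b (0.071-fold, adjusted p = 3.07e-18), Gchfr (0.142-fold, adjusted p = 1.25e-12) and Psmc3ip (0.265-fold, adjusted p = 2.41e-11) were lower as without induction. Rarres1 (0.208-fold, adjusted p = 1.76e-05) and H2-Q2 (0.26-fold, adjusted p = 3.63e-05) were lower as well.

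The other lists are given with members past the test over all genes, the median, the camera adjusted p, and the adjusted p with an estimated correlation where the preset one passed. Luminal epithelium genes lay higher (0 of 16, 0.44, 0.00017, adjusted p = 0.63 with an estimated correlation). Basal and myoepithelial genes lay higher (0 of 14, 0.29, 0.00017, adjusted p = 0.63 with an estimated correlation). Proliferation genes had 1 of 37 higher and 2 adjusted over the list alone (0.37, 3.83e-11, adjusted p = 0.63 with an estimated correlation). Interferon response genes had 1 of 23 higher and 1 adjusted over the list alone (0.06, 0.0218, adjusted p = 0.792 with an estimated correlation). Senescence-associated genes had 1 of 11 higher and 1 adjusted over the list alone (0.11, 0.0191, adjusted p = 0.63 with an estimated correlation). White adipocyte genes had 1 of 14 lower and 6 adjusted over the list alone (-0.44, 0.0191, adjusted p = 0.79 with an estimated correlation). Endothelium genes had 1 of 10 lower and 3 adjusted over the list alone (-0.38, 0.0191, adjusted p = 0.79 with an estimated correlation). Mitochondrially encoded genes had 1 of 13 lower and 1 adjusted over the list alone (-0.37, 0.0447, adjusted p = 0.792 with an estimated correlation). Immediate early genes had 0 of 14 past the test (0.08, 0.046, adjusted p = 0.792 with an estimated correlation).

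Cholesterol synthesis had 1 of 15 lower and 1 adjusted over the list alone (median -0.20, camera adjusted p = 0.317). Schwann cells and nerve had 0 of 8 over all genes, and 1 higher and 3 lower adjusted over the list alone (-0.39, 0.281). Skeletal muscle (0 of 16, -0.43, 0.556), fibroblasts and matrix (0 of 16, -0.37, 0.251) and skin keratinocytes (0 of 7, -0.29, 0.372) had none past the test. Granulocytes (0 of 3, 0.09, 0.136) and salivary gland (0 of 3, 0.01, 0.235) had none either, and macrophages had 0 of 14 over all genes and 1 lower adjusted over the list alone (0.03, 0.227). For T cells (0 of 14, camera adjusted p = 0.281) the median was -0.02 and the mean -0.01, while the test against other genes pointed upward. So it did for B cells (0 of 11, median -0.10, mean -0.07, 0.48) and the circadian clock (0 of 12, median -0.09, mean -0.07, 0.486). The integrated stress response had 1 of 12 higher and 1 adjusted over the list alone, with a median of -0.07 and a mean of 0.07 (0.235).

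In all 238 genes were higher and 601 lower in long-induced glands of the Esr1 model (3551 at an unadjusted p under 0.05), 28.4% higher, and the median of all genes differed by -0.12. After rescaling 1033 were higher and 956 lower, 51.9% higher, among them 238 and 525 of the same genes. A fit of the compared groups alone called 1595 genes. By exact permutation within strata the fatty acid synthesis score differed, at 5.47 ± 0.478 against 6.49 ± 0.413 (difference -1.02, p = 0.0005, adjusted p = 0.0109). Oxidative phosphorylation (-0.49, adjusted p = 0.0109) and brown adipocyte scores (-1.05, adjusted p = 0.0362) differed too. The milk score did not pass, at 5.47 ± 1.75 against 3.41 ± 1.02 (difference 2.06, exact p = 0.0075, adjusted p = 0.0544). It exceeded the luminal epithelium score by 1.70 more in the Esr1 model (exact stratified permutation p = 0.0095, a test chosen after the values were seen). Of 36 named calls 19 held without any 1 of the 18 libraries, Fasn, Acaca, Elovl6, Scd1, Wap and Glycam1 included. Those of Csn2, Csn1s1, Csn1s2a, Lao1 and Wfdc18 were lost without at least 12 of the 18, with an adjusted p of 0.0922 for Csn2 without replicate 1 of the 30-month Esr1 glands. Without the libraries rich in ribosomal RNA the adjusted p was 0.088 for Csn2 and 0.0742 for Wap. Both comparisons of the models shared 259 genes, 258 with the same sign, where independent lists would share 4.7 higher and 5.9 lower genes.

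**Figure D4:**
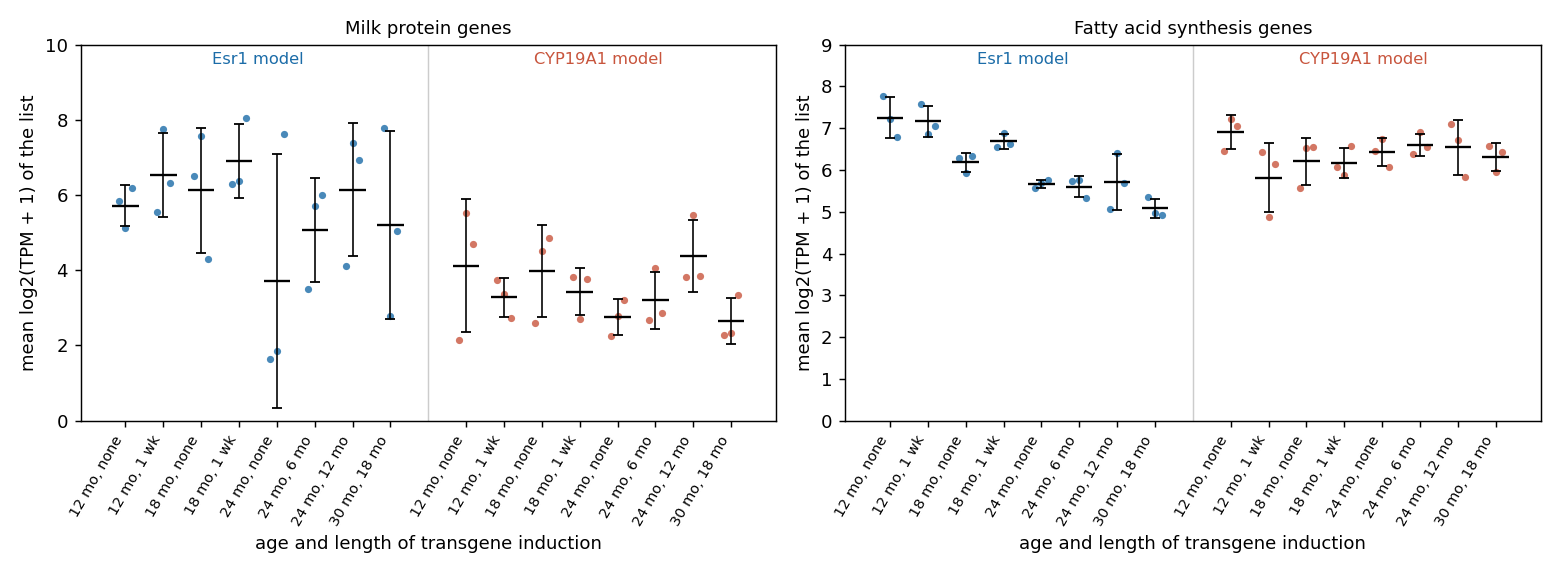
Mean log2(TPM + 1) of milk protein genes (left) and fatty acid synthesis genes (right) for each library by age and length of induction (points, libraries; black bars, means of 3; whiskers, SD). In long-induced glands the fatty acid synthesis score averaged 5.47 in the Esr1 and 6.49 in the CYP19A1 model, and the milk score 5.47 and 3.41, with milk scores of single Esr1 libraries far apart.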

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

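The differences between the models in their change with age, for 24 against 12 months and for 30 against 24 months, were tested only after the data had been seen, and the genes outside the naming rule were chosen after their values were seen. Each is given here because the change differed between the groups of both models.

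From 12 to 24 months without induction, 8 genes changed differently in the models (1311 at an unadjusted p under 0.05; median of all genes -0.32), and all 8 were among the 21 called after rescaling. Cd300ld3, a receptor gene of myeloid cells, rose more in the Esr1 model (log2 difference 1.90, limma adjusted p = 5.33e-06), as did the ribosomal protein gene Rpl34 (3.80, adjusted p = 0.0014), 5830417I10Rik (1.68, adjusted p = 0.00208) and Gm43609 (0.92, adjusted p = 0.00271). The change was lower in the Esr1 model for BC002163 (-4.37, adjusted p = 0.000163), Gm15920 (-4.85, adjusted p = 0.00245), Gm18666 (-1.39, adjusted p = 0.0192) and Gm7879 (-2.61, adjusted p = 0.0204). Leaving out single libraries gave 6 to 12 genes. Of 100 splits of the libraries, 18 gave as many genes and the highest other gave 7588, so chance cannot be excluded for the count, and the high split points to a structure of the samples. From 24 to 30 months with induction, 1 gene changed differently, Cd300ld3 (-1.25, adjusted p = 0.0409; 295 at an unadjusted p under 0.05; median of all genes -0.19), a call lost without any of 9 single libraries and after rescaling (adjusted p = 0.365); 12 of 100 splits gave as many and the highest other 28, so chance cannot be excluded there either. In the Esr1 model Cd300ld3 lay at 3.17, 4.03 and 3.15 TPM at 24 months after 0, 6 and 12 months of induction and at 0.71 TPM at 30 months, while no 12- or 18-month group of that model exceeded 0.09 TPM and no CYP19A1 group 0.29 TPM.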

How the results depend on the processing

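The fits without libraries rich in ribosomal RNA and without the library low in Xist, the averaged induction effects and the models' differences in change with age were chosen after the results were seen; the other alternatives were planned. The depth, unknown beyond the stated minimum, limits the scarce genes, and for no value below was the cause tested. Counts of genes follow.

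With a pseudocount of 0.1, 1 week of Esr1 induction at 12 months gave 1 gene, 12 months of CYP19A1 induction 0, CYP19A1 18 against 12 months 0 and the models' difference at 30 months 0. Without a filter, Esr1 induction gave 109 and 11 genes for 1 week at 12 and 18 months, 11 and 7 for 6 and 12 months, and CYP19A1 induction 224, 8, 8 and 35. Without a filter, age gave 81 and 316 in the Esr1 and 136 and 1414 in the CYP19A1 model, 30 against 24 months 46 and 13, the differences in response 3 for 1 week and 3 for long induction, the averaged Esr1 induction 10, and the models' differences in change with age 5, 19 and 4; more genes were tested there.

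After median-of-ratios rescaling, Esr1 induction gave 0 for 1 week at 12 months and 0 for 12 months, age 363 in the Esr1 model at 24 months, and 0 and 65 in the CYP19A1 model. Rescaled, the models differed in 3379 genes uninduced and 1989 long-induced, in their change by 24 months in 21 and at 30 months in 0, and the averaged Esr1 transcript change was -0.008. In a fit of the compared groups alone, 1 week of Esr1 induction gave 4 and 2 at 12 and 18 months, 12 months of induction 0 in both models, 24 against 12 months 24 (Esr1) and 3 (CYP19A1), CYP19A1 18 against 12 months 0, and 30 months 0 (Esr1) and 2 (CYP19A1). In that fit the models differed in 211 genes uninduced and 1595 long-induced, the averaged CYP19A1 induction gave 1, and the differences in change with age 4 and 0 at 24 and 30 months.

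With the replicate number as a block, 12 months of Esr1 induction gave 2, 24 against 12 months 76 (Esr1) and 1525 (CYP19A1), CYP19A1 18 against 12 months 1, CYP19A1 30 months 1 and the models' difference at 30 months 0. Without libraries rich in ribosomal RNA, CYP19A1 induction gave 2 for 1 week at 18 months and 2 for 6 months, 24 against 12 months 266 (Esr1) and 7 (CYP19A1), CYP19A1 18 against 12 months 0, Esr1 30 months 85, the models 2569 uninduced and their difference by 24 months 4; 12-month CYP19A1 induction, the averaged CYP19A1 induction and the 1 week difference could not be fitted. The CYP19A1 age counts, the uninduced models and the difference by 24 months rest there on 1 library of the 12-month CYP19A1 glands, assumed to vary like the other groups. Without the library low in Xist, CYP19A1 induction for 1 week at 18 months gave 1.

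With the skeletal muscle score as a covariate, 1 week of Esr1 induction at 12 months gave 0, CYP19A1 age 0 and 12, Esr1 30 months 105, the models 1771 uninduced and their difference by 24 months 13. This covariate is the list's own mean, so by construction the muscle medians went to 0.023 for 1 week of Esr1 induction at 12 months, -0.003 and -0.089 for CYP19A1 age at 18 and 24 months, 0.035 for the uninduced and 0.049 for the long-induced models, and Tnni2 in CYP19A1 age to -0.029. The oxidative phosphorylation median there went to 0.47 from 0.80, with the test against other genes pointing down (adjusted p = 0.822), and the cause was not tested.

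Leaving out 1 library at a time, where a group of 2 is assumed to vary like the others, gave these ranges. Esr1 induction: 0 to 7, 0 to 10, 0 to 6 and 0 to 9; CYP19A1 induction: 0 to 12421, 0 to 1, 0 to 3 and 0 to 8; averaged: 0 to 11 and 0 to 1. Age at 18 and 24 months: 0 to 2 and 62 to 153 (Esr1), 0 to 11 and 239 to 3374 (CYP19A1); 30 months: 2 to 42 and 0 to 5. Models: 411 to 1349 uninduced and 591 to 995 long-induced. Differences in response: 0 to 6988 and 0 to 1; in change with age: 0 to 0, 6 to 12 and 0 to 1. The Esr1 transcript changed by 0.09 to 0.45, 0.25 to 0.71, -0.37 to -0.06 and -0.57 to -0.07 in its 4 comparisons and by 0.07 to 0.23 averaged. Of 119 calls of named genes, 51 held in every fit that left out a library and 35 in every other alternative.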

Other observations

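Of the tests given here, all exact tests of list scores, those of the title naming, the white adipocyte share and the scaling for fatty acid synthesis genes included, and that of Y-linked genes for the library low in Xist, were chosen after the result was seen.

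In uninduced glands, gene lists of several cell types leaned to 1 side between the models, though none passed with an estimated correlation. Endothelium genes lay lower in the Esr1 model (0 of 10 past the test, 0 adjusted over the list alone, 9 after rescaling; median -0.42; camera adjusted p = 4.56e-06; adjusted p = 0.789 with an estimated correlation), as did white adipocyte genes (0 of 14; -0.29; 0.000511; adjusted p = 0.789 with an estimated correlation) and plasma cell genes (1 of 12 and 2 adjusted over the list alone; median -0.30; 0.000511; adjusted p = 0.789 with an estimated correlation), of which Ighg1 was lower (0.267-fold, adjusted p = 0.0203). Mitochondrially encoded genes lay higher (1 of 13, mt-Nd3, and 8 adjusted over the list alone; median 0.54; adjusted p = 0.789 with an estimated correlation), beside oxidative phosphorylation genes (1 of 18, Cox7b, and 3; 0.32; adjusted p = 0.789 with an estimated correlation). Skeletal muscle genes lay higher with them (0 of 16; median 0.85; camera adjusted p = 0.0417; adjusted p = 0.899 with an estimated correlation). In long-induced glands, all of 24 months or older, oxidative phosphorylation genes lay the other way (median -0.49). The uninduced comparison averages 12, 18 and 24 months, so this contrast mixes age with induction. From 12 to 24 months without induction, their median moved by 0.80 in the CYP19A1 and by -0.15 in the Esr1 model. That of skeletal muscle genes moved by 3.98 and 1.13. The 12-month CYP19A1 glands, with libraries rich in ribosomal RNA, thus weigh in the uninduced difference.

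Milk gene scores varied between libraries of 1 group. Uninduced 24-month Esr1 glands had milk scores of 1.65, 1.86 and 7.62, and Csn2 had a log2 change of -6.18 from 12 to 24 months (adjusted p = 0.288) although its mean TPM was 3070 ± 5314 against 2703 ± 439. Milk genes there had 0 of 17 past the test and 5 lower adjusted over the list alone (median -1.77; camera adjusted p = 0.000463; adjusted p = 0.664 with an estimated correlation). White adipocyte genes lay lower from 12 to 18 months in the Esr1 model (0 of 14, 3 adjusted over the list alone; median -0.89; camera adjusted p = 2.64e-16; adjusted p = 0.0529 with an estimated correlation), and fatty acid synthesis genes in the CYP19A1 model (0 of 15 and 2; -0.89; 6.06e-15; adjusted p = 0.0964 with an estimated correlation).

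A first pattern is the set of 258 genes that differed between the models with the same sign in uninduced and in long-induced glands. Variants linked on chromosomes, from different genetic backgrounds of the lines, may account for part of it. Of its 138 protein-coding genes with a position, 65.9% had another within 5 Mb, against a median of 50.7% and a highest value of 64.5% in 1000 random sets of tested protein-coding genes. Between 170 and 180 Mb of chromosome 1, 7 of 94 tested genes belonged to the set (Ifi202b, Mndal, Ifi205, Ifi206, Ifi213, Atp1a4 and Cfap126), and between 30 and 40 Mb of chromosome 17, 6 of 175, H2-Q2 among them. Clusters of co-regulated paralogs would also lie close together, and the labels name no strain, so an effect of the transgenes themselves stays open and untested.

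A second pattern is the lower fatty acid synthesis score at 24 than at 12 months over both models (difference -1.03, exact permutation p = 0.015, adjusted p = 0.145 over the lists). A batch that follows the title naming would spare the 18-month libraries, yet these already lay lower than the 12-month ones (-0.89, exact p = 0.015), but relative to the white adipocyte score this held in the CYP19A1 model (-1.16, SE 0.42) and not beyond the spread in the Esr1 model (-0.24, SE 0.25), so a batch stays open there. A smaller share of white adipocytes is argued against by the white adipocyte score (0.13, exact p = 0.64), since the fatty acid synthesis score fell beyond it (-1.17, exact p = 0.005), and TPM scaling by the rescaled score (-1.16, exact p = 0.005, the smallest p these strata allow). Across the naming boundary, 24 against 18 months, the score differed by -0.15 over both models (exact permutation p = 0.515), but the models moved in opposite directions. In the Esr1 model the scores fell without overlap, from 6.29, 5.92 and 6.34 at 18 months to 5.57, 5.69 and 5.75 at 24 months. In the CYP19A1 model they were 5.56, 6.52 and 6.56, then 6.46, 6.74 and 6.08. The step in the Esr1 model alone was not tested, and it coincides with the naming boundary. The 18-month values cannot show that no batch adds to the 24-month ones. An age-related decline in lipid synthesis is a candidate explanation that stays open, but both comparisons with 12 months rest on the same 12-month libraries. The share of brown adipocytes was not tested. From 12 to 24 months their genes had a median of -0.58 in the Esr1 model (camera adjusted p = 0.664 with an estimated correlation). In the CYP19A1 model it was -0.31 (camera adjusted p = 0.897 with an estimated correlation). Feeding state and cage, which the labels do not give, were not tested.

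Another pattern is 1 library, replicate 2 of the 18-month CYP19A1 glands induced for 1 week, with Xist, the RNA that silences the second X chromosome, at 0.30 TPM against 18.5 to 97.0 TPM in the 47 others. Tissue of a male is argued against by the summed Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, at 0.04 TPM against 0 to 0.16, and poor capture of long noncoding RNA by Malat1, Neat1, Meg3, Kcnq1ot1 and Norad, at a mean of 6.37 on the log2 scale against 5.68 to 6.77. A missing second X chromosome may account for it: the genes that escape X inactivation averaged 4.41 against 4.91 to 5.37, and Kdm6a, Kdm5c, Eif2s3x and Ddx3x each lay below all 47 others. Without this library 1 week of CYP19A1 induction at 18 months gave 1 gene in place of 0. Whether the loss was in the animal or in the sampled cells stays open.

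Other splits of the libraries were counted for each comparison. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For Esr1 induction the real and the highest other counts were 2 and 5 (1 week at 12 months), 0 and 2 (18 months), 0 and 46 (6 months) and 1 and 126 (12 months), and for CYP19A1 induction 0 and 14334, 0 and 0, 0 and 0, and 4 and 1. For age they were 0 and 759 (18 months) and 116 and 2 (24 months) in the Esr1 model, 2 and 12541 and 857 and 7303 in the CYP19A1 model, and 28 and 4 (Esr1) and 0 and 1 (CYP19A1) for 30 against 24 months. In the splits with 14334, 12541 and 7303 genes replicate 1 of the uninduced 12-month CYP19A1 glands, the library with the highest ribosomal RNA share, stood opposite to replicates 2 and 3 of its group, and those with 46 and 126 put replicates 1 and 2 of the uninduced 24-month Esr1 glands together, so they point to a structure of the samples. For the models after long induction 1 of 100 splits, the real one, gave as many as the real 839 genes and the highest other gave 44. This argues against chance for that count but does not exclude it. A share of 1 in 100 is the smallest that these splits allow, and 23 results were put through them. The splits also take the libraries to be separate mice, which the titles do not say. Without induction 3 of 100 splits gave as many as the real 596, and the highest other gave 1516, which again points to a structure of the samples, so chance is not firmly excluded there. For the differences in response and in change by 18 months and for the averaged inductions the real count was 0, which all 100 splits reach by necessity, so the splits decide nothing there, with highest others of 10169 (1 week), 72 (long induction), 13308 (18 months), 12 (Esr1) and 13627 (CYP19A1).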
